A study of Homo sapiens with 6 samples.

How the data were processed

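RNA from BJ human fibroblasts was analysed in 6 libraries, 2 each of young cells, senescent cells and senescent cells treated with 10 µM SB203580 for 48 h. Per the labels' protocols, total RNA was selected for poly-A and made into single-end libraries with a TruSeq version 2 kit. This kit type does not mark strand, and whether the counting used strand is not given in the sources used here, so genes that overlap on opposite strands cannot be told apart and antisense genes are not named. Per the submitters' processing notes, the tools used were TopHat2 2.0.6, Bowtie2 2.0.6, Cufflinks 2.02 and edgeR, with genome build hg19; the program that counted reads per gene is not given in the sources used here.

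The authors deposited, for each library, whole-number counts per gene symbol, which are not normalized and sum to between 19088224 and 21807436, over 50651 rows of which 15053 were 0 in all 6 libraries. The authors also deposited Cufflinks tables with columns named FPKM, whose values are treated here as a score, normalized by the authors in a way not given in the sources used here. These values sum to between 4.68e+13 and 1.25e+14 in a library, so they are not on the scale of FPKM. Only 244 of 11877 genes with a mean count of 50 or more (2.05%) carried a gene name in all 6 Cufflinks tables, so these values entered no test. Positions given for genes are the loci of those tables on hg19, 1-based. Of the 50651 symbols 27034 matched a current or older symbol in the RefSeq gene table of GRCh38.p14, which was used for names and gene types only.

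Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr by group, leaving 16290, library sizes were scaled by TMM, and all 6 libraries were fitted together without covariates, which leaves 3 residual degrees of freedom (prior degrees of freedom 6.84, common biological coefficient of variation 0.0927). The 3 comparisons were tested with the quasi-likelihood F test and called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. The standard error of a log2 fold change is its size divided by the square root of F. CPM values use the TMM-scaled library sizes. Libraries of a state were compared before use; their counts differed by more than counting noise (chi-square per degree of freedom from 14.2 to 16.7), which does not show whether they came from separate cultures or from repeated preparations of 1 culture. At these depths, with counts simulated from the observed means, library sizes and dispersions and 50 genes changed at each size, a 2-fold change was called the right way in 72% for senescent against young (15897 genes), 72% for inhibitor against senescent (15872 genes) and 74% for inhibitor against young (15881 genes), and a 1.5-fold change in 42%, 38% and 36%. In these simulations 6.70%, 8.04% and 5.53% of calls were of unchanged genes. They held 194, 199 and 199 calls, fewer than the 4332, 661 and 3965 of the data, so their adjusted threshold was stricter. The simulated shares may therefore understate those of the data.

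Before the data were examined, 30 gene lists of 682 distinct genes were written from textbook knowledge, together with the rule for naming genes and the alternatives to try. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists of a comparison, and again with an estimated correlation and with fry. Counts "adjusted over the list alone" repeat the Benjamini-Hochberg adjustment on the list's genes only. In all 13 list genes were listed at 0 in every library, among them MMP3 and TNF but also the ribosomal protein gene RPS25, so a 0 is not read as absence of expression. Where a gene had 0 counts in a state, the fold is a lower bound against 3 counts over the group, and with 1 to 3 counts an exact binomial interval is given, which covers counting error only. The medians of the lists holding such a gene were the same with the gene at its bound.

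Genes were named by rule: for each comparison the 10 largest positive and 10 largest negative log2 fold changes among called genes whose 2 libraries of one state both lay above the 2 of the other and whose higher state averaged at least 5 CPM; up to 4 called genes of each list described; a fixed set of 19 senescence, SASP and p38 genes, of which MMP3 was listed at 0; and the 10 largest opposite changes with the inhibitor in each direction. Y-linked genes, unnamed loci, antisense transcripts and pseudogenes are not named. Some members of lists are named only in counts of calls, and genes of the closing section were chosen after their values were seen.

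Correlations and covariances of fold changes between comparisons that share libraries were set against 20 simulations of unchanged groups. Alternatives were DESeq2 1.42.0, RLE factors, total counts only, other low-count filters, the replicate number as a block, fits of only the 2 states compared, and leaving out each library in turn, where a state left with 1 library is assumed to vary like the others. Planned limma tests on the FPKM values were not run for the reasons above. Gene spans and exon lengths came from GENCODE version 29 and were used as properties of genes, with no coordinates taken from it. Figures were drawn with matplotlib 3.10.9.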

Results

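Messenger RNA was measured by RNA-seq in BJ cells, a line of normal human fibroblasts with a limited lifespan in culture, in 3 states with 2 libraries each. These were young cells, senescent cells, and senescent cells given 10 µM SB203580 for 48 h with the compound renewed every day. Senescence is a lasting arrest of division, and senescent fibroblasts are known for secreting cytokines, chemokines and proteases, the senescence-associated secretory phenotype (SASP). SB203580 inhibits the p38 mitogen-activated protein kinases. Each label ends in a number shared by all libraries and then in 11 or 24, and each of the 3 states has both. The libraries are named here by this last number. What the numbers mark is not stated, and the main fits do not use them as a pairing. Libraries of the same number did share differences across states. On the third axis of a principal component analysis all libraries numbered 11 were positive and all numbered 24 negative. Total gene counts ran from 19088224 (senescent 11) to 21807436 (senescent 24). They were 20685679 and 19917125 in young 11 and 24 and 20930634 and 21001045 in inhibitor-treated 11 and 24. The labels do not say whether the libraries of a state came from separate cultures, so p-values measure only the spread between these libraries, which can be technical. Levels are in CPM (counts scaled to a common library total), as the mean ± SD of the 2 libraries. Log2 fold changes are given ± SE. Adjusted p-values are from edgeR for genes and from camera for lists.

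The first comparison asked what differs between senescent and young cells. Chemokine and cytokine genes were among the largest gains in the senescent cells. CXCL1, a neutrophil chemokine (hg19 chromosome 4, 74735110 to 74736959), rose from 4.71 ± 0.499 CPM in young to 108 ± 0.804 CPM in senescent libraries (log2 fold change 4.51 ± 0.18, adjusted p = 1.56e-06). IL8, another neutrophil chemokine (hg19 chromosome 4, 74606223 to 74609433), rose from 3.87 ± 0.373 to 81.9 ± 3.6 CPM (adjusted p = 4.31e-06). Genes of cell division fell, such as the mitotic kinesin gene KIF20A, from 58.6 ± 21.6 to 4.74 ± 2.56 CPM (log2 fold change -3.65 ± 0.34, adjusted p = 6.6e-05, and -4.31 to -3.15 with 1 library left out). CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases, rose from 242 ± 1.84 to 1340 ± 172 CPM (2.48 ± 0.13, adjusted p = 3.88e-06). Of 16290 genes tested, 2213 were called higher and 2119 lower in senescent cells, of which 592 and 676 differed by more than 2-fold. With total counts in place of TMM factors the split turned, to 1877 higher and 2343 lower. Of 28 lists with at least 5 tested genes, 13 were called by camera, 0 by camera with an estimated correlation and 16 by fry.

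Of 47 measured SASP genes, 37 rose and 2 fell, with a median log2 fold change of 1.89 (camera adjusted p = 1.65e-47, and adjusted p = 0.0581 with an estimated correlation). Adjusted over the list alone, 38 rose and 3 fell. Besides CXCL1 and IL8, CXCL6 rose by a log2 fold change of 3.90 ± 0.23. IL1B, a central inflammatory cytokine, rose from 2.96 ± 1.78 to 37.8 ± 1.15 CPM (3.65 ± 0.27, and 3.17 to 4.47 with 1 library left out). CCL2, a monocyte chemokine, rose by 1.89 ± 0.15 to 254 ± 2.92 CPM. IL6 rose less, from 13.2 ± 4.24 to 28.8 ± 0.879 CPM (1.13 ± 0.18, adjusted p = 0.00133). The interstitial collagenase gene MMP1 rose from 189 ± 51.3 to 802 ± 116 CPM (2.09 ± 0.18). IL1A reached 4.72 ± 0.157 CPM from 0.916 ± 0.0487 (2.36 ± 0.24). CCL20 had 0 counts in the young libraries and 28 in the senescent ones together, at least 9.52-fold higher against a floor of 3 counts over the group. Among 31 messenger RNAs with AU-rich elements, 17 of which are also SASP genes, 23 rose and 4 fell (median 1.89, camera adjusted p = 8.59e-30, and adjusted p = 0.0581 with an estimated correlation). The counts adjusted over the list alone were the same numbers. Feedback targets of NF-kB, the transcription factor of many inflammatory genes, rose in 13 of 23 and fell in 1 (median 0.54, camera adjusted p = 1.22e-06, and adjusted p = 0.131 with an estimated correlation). Adjusted over the list alone, 14 rose and 1 fell. SOD2 went from 272 ± 47.8 to 872 ± 70.1 CPM and BIRC3 from 6.05 ± 1.07 to 24.3 ± 0.513 CPM. CXCL1, CXCL2 and CXCL3 are close in sequence. How shared reads were assigned is not given in the sources used here, so their separate levels are uncertain.

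Of 40 cell-cycle and mitosis genes 39 fell, both over all genes and adjusted over the list alone, with a median log2 fold change of -2.60 (camera adjusted p = 1.18e-93, and adjusted p = 0.111 with an estimated correlation). CDC20, the activator of the anaphase-promoting complex, fell from 24.4 ± 3.44 to 2.42 ± 0.396 CPM, and DLGAP5, a spindle protein gene, from 27.9 ± 3.97 to 2.59 ± 0.965 CPM. MKI67, the usual marker of dividing cells, went from 82.7 ± 21.4 to 9.07 ± 5.25 CPM (-3.20 ± 0.31, adjusted p = 7.24e-05, and -3.94 to -2.69 with 1 library left out). In the DNA replication list 20 of 39 fell and 3 rose, with 22 lower and 3 higher adjusted over the list alone (median -0.41, camera adjusted p = 9.49e-05, and adjusted p = 0.248 with an estimated correlation). Thymidine kinase TK1 fell from 37.2 ± 10.1 to 4.50 ± 2.09 CPM, while PCNA, which is also induced by p53, rose from 49.7 ± 2.8 to 124 ± 25 CPM. Replication-dependent histone genes fell in 23 of 26 and rose in 1, the same numbers as adjusted over the list alone (median -1.13, camera adjusted p = 3.19e-18, and adjusted p = 0.248 with an estimated correlation). These genes are near-identical copies lacking poly-A tails, so their levels are uncertain after poly-A selection. The lamina and chromatin list held 11 of 17 lower genes, 13 adjusted over the list alone (median -0.59, camera adjusted p = 6.94e-10, and adjusted p = 0.0581 with an estimated correlation). In it LMNB1, the nuclear lamin B1, fell from 28.5 ± 1.45 to 6.25 ± 1.6 CPM (-2.19 ± 0.17, adjusted p = 1.86e-05) in senescent cells. HMGB2, a chromatin protein, fell from 56.7 ± 2.47 to 12.2 ± 1.77 CPM (-2.22 ± 0.12, adjusted p = 4.31e-06).

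Of 30 p53 target genes 28 rose and none fell, also when adjusted over the list alone (median 1.21, camera adjusted p = 2.04e-46, and adjusted p = 0.131 with an estimated correlation). Beside CDKN1A these included MDM2, the ubiquitin ligase of p53, from 95.1 ± 9.79 to 451 ± 41.4 CPM, GDF15 from 17.4 ± 5.59 to 94.3 ± 6.45 CPM, and TNFRSF10C from 3.11 ± 0.652 to 19.9 ± 2.31 CPM. CDKN2A, which encodes p16 and ARF, was lower in senescent cells, at 4.70 ± 1.13 against 9.85 ± 1.2 CPM (-1.06 ± 0.21, adjusted p = 0.00515). CDKN2B stood at 13.7 ± 1.58 against 11.6 ± 1.57 CPM (adjusted p = 0.252), and GLB1, the gene of lysosomal beta-galactosidase, at 91.2 ± 0.532 against 85.7 ± 1.87 CPM (adjusted p = 0.491), neither past the test. In the list of CDK inhibitors and retinoblastoma family genes 1 of 11 rose and 6 fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.0462, and adjusted p = 0.443 with an estimated correlation). Among them CDKN2C fell (log2 fold change -2.35 ± 0.15). This list lost its call without young 24 (adjusted p = 0.0559) and without senescent 11 (adjusted p = 0.126).

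Further groups differed by less. Lysosome genes rose in 11 of 27 and fell in 1, also adjusted over the list alone (median 0.19, camera adjusted p = 0.000271, and adjusted p = 0.242 with an estimated correlation). Cathepsin S (CTSS) went from 3.78 ± 0.0374 to 15.1 ± 0.981 CPM. Collagen and matrix genes fell in 11 of 33 and rose in 3, or 12 and 3 adjusted over the list alone (median -0.19, camera adjusted p = 0.00714, and adjusted p = 0.145 with an estimated correlation). COL11A1 went from 258 ± 31.2 to 86.9 ± 3.55 CPM. Genes of cholesterol and fatty acid synthesis fell in 11 of 32 and rose in 1, also adjusted over the list alone (camera adjusted p = 0.0113, and adjusted p = 0.571 with an estimated correlation). The list's call was lost without senescent 24 (adjusted p = 0.0802). Immediate-early genes went both ways, 11 of 29 up and 5 down, or 11 and 6 adjusted over the list alone, with DUSP4 at 2.13 ± 0.13 and FOS at -4.62 ± 0.72. For this list the median was -0.02 while the mean was 0.08 and the test pointed up (camera adjusted p = 0.00258, and adjusted p = 0.133 with an estimated correlation). FOS rested on unequal young libraries, at 90.6 ± 87.5 CPM, against 3.64 ± 1.77 in senescent ones. Its log2 fold change was -2.96 without young 11 and -5.36 without young 24, and lay between these without senescent 24. Of the p38 pathway genes, MAP2K6, which encodes the p38-activating kinase MKK6 (hg19 chromosome 17, 67410838 to 67538451), fell from 17.6 ± 3.25 to 2 ± 0.922 CPM (-3.11 ± 0.28, adjusted p = 5.23e-05). MAPK14, the gene of p38 alpha, stood at 81.1 ± 3.16 against 80.3 ± 1.21 CPM (adjusted p = 0.913). ZFP36, a protein that destabilises messenger RNAs with AU-rich elements, fell from 20.7 ± 0.557 to 9.22 ± 0.193 CPM (-1.17 ± 0.12, adjusted p = 8.5e-05). HNRNPD, which binds the same elements, stood at 19.7 ± 3.61 against 24.2 ± 0.0948 CPM (adjusted p = 0.181).

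The largest gains by the fixed rule also included CLCA2, from 2.61 ± 0.644 to 168 ± 54.1 CPM, the tight-junction gene CLDN1 (log2 fold change 5.40 ± 0.27), PLCH1 (4.75 ± 0.31) and the decoy receptor IL13RA2 (4.58 ± 0.42). The value of CLDN1 ran from 4.94 to 6.04 with 1 library left out. That of IL13RA2, with 14 and 2 counts in the young libraries, was 6.46 without young 11 and 3.84 without young 24. Some markers of other cell types also differed. Of 9 keratinocyte markers 3 rose, or 4 adjusted over the list alone, such as KRT16 from 0.378 ± 0.252 to 2.21 ± 0.0324 CPM (log2 fold change 2.51 ± 0.40, and 1.99 to 3.43 with 1 library left out). KRT17 rose by 2.13, and by 1.09 to 2.69 with 1 library left out, but was not called by DESeq2 (adjusted p = 0.0865). Of 7 leukocyte markers 3 rose, also adjusted over the list alone, such as PTPRC from 0.718 ± 0.166 to 2.07 ± 0.0906 CPM and CD68 from 86 ± 16.8 to 146 ± 5.03 CPM. Neither list passed camera (adjusted p = 0.0518 and 0.151). TYRP1 of the melanocyte list had 3 counts over the young libraries and 28 over the senescent ones, a ratio of 9.52 with an exact counting interval of 2.94 to 49.0, and MITF of the same list fell from 54.3 ± 2.99 to 30.5 ± 1.35 CPM. All 3 of these young counts of TYRP1 were in young 24, and without young 11 its log2 fold change went from 3.14 to 2.15 and its call was lost (adjusted p = 0.0687). Of 16 fibroblast markers 1 rose and 4 fell, or 2 and 4 adjusted over the list alone (median 0.05 but mean -0.03, camera adjusted p = 0.697). Every called gene but 1 had the same sign in the libraries numbered 11 and in those numbered 24 (4331 of 4332). Calling from these same libraries favours such agreement, so it is not separate support. Of 128 called genes named for this comparison by the fixed rule, 106 kept their call in each of the 6 fits that leave out 1 library.

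**Figure D1:**
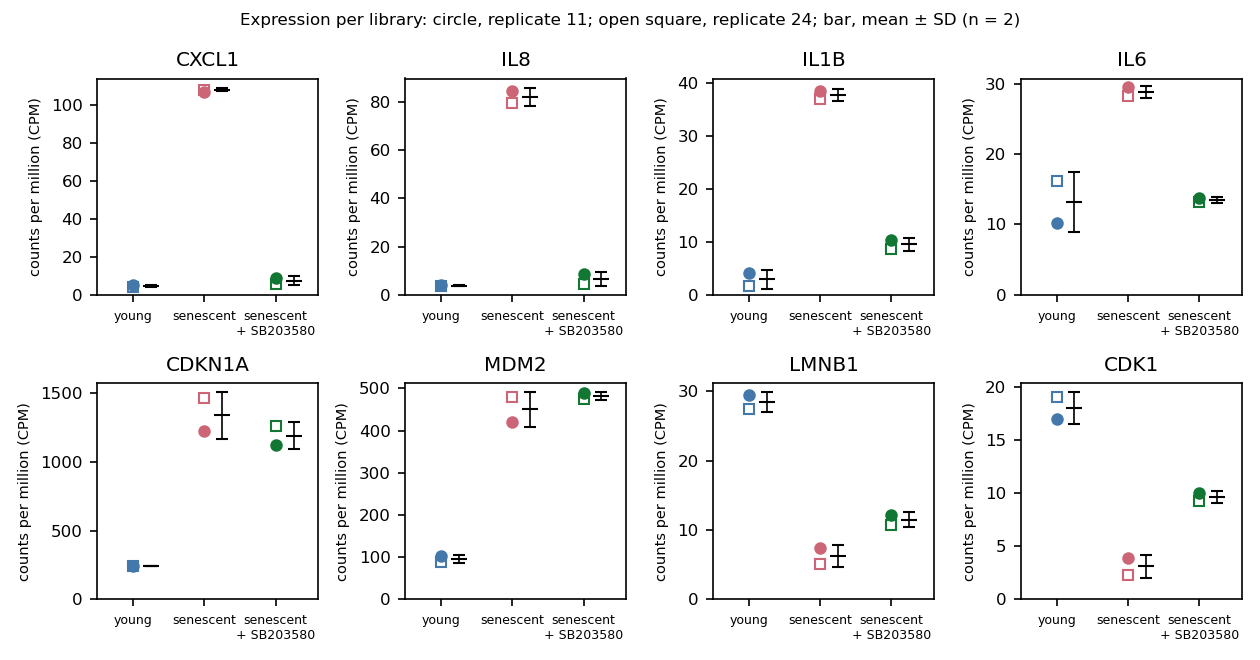
Each panel plots the expression of 1 gene in CPM (vertical axis, from 0) in young, senescent and SB203580-treated senescent libraries, with replicate 11 as a filled circle, replicate 24 as an open square, and the mean ± SD (n = 2) as a black bar. CXCL1 averaged 4.71, 108 and 7.43 CPM in the 3 states, CDKN1A 242, 1340 and 1190 CPM, and CDK1 18.0, 3.11 and 9.65 CPM.

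The next comparison asked what differed between senescent cells with and without SB203580. No vehicle or mock treatment is given for the untreated senescent cells in the sources used here. Effects of solvent or of the daily renewal therefore cannot be told apart from those of the compound. Several chemokine and cytokine genes that were high in senescence were among the largest drops, though the largest by the fixed rule was that of the hormone subunit gene CGA. CXCL1 fell from 108 ± 0.804 to 7.43 ± 2.37 CPM (log2 fold change -3.85 ± 0.17, adjusted p = 1.26e-05). IL8 fell from 81.9 ± 3.6 to 6.61 ± 2.98 CPM (-3.62 ± 0.22, adjusted p = 4.29e-05). IL1A (hg19 chromosome 2, 113531492 to 113542167) fell from 4.72 ± 0.157 to 0.441 ± 0.0841 CPM (-3.41 ± 0.28, adjusted p = 0.00026). Cell-cycle genes rose, such as CDK1, the mitotic cyclin-dependent kinase, from 3.11 ± 1.11 to 9.65 ± 0.568 CPM (1.64 ± 0.21, adjusted p = 0.00308). CDKN1A stood at 1190 ± 98.1 against 1340 ± 172 CPM and did not pass the test (-0.17 ± 0.12, adjusted p = 0.53). In all, 345 genes were called higher and 316 lower with the inhibitor, 98 and 134 of them by more than 2-fold. With total counts in place of TMM factors the split turned, to 262 higher and 324 lower. With the replicate number as a block, 889 genes were called higher and 722 lower. Of 28 lists 15 were called, and 4 with an estimated correlation.

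Of the 47 SASP genes 26 fell and 2 rose with the inhibitor, or 35 and 5 adjusted over the list alone (median -0.99, camera adjusted p = 5.55e-63), and this call held with an estimated correlation (adjusted p = 0.0204). CXCL6 fell from 34.2 ± 7.88 to 3.16 ± 0.444 CPM and IL1B from 37.8 ± 1.15 to 9.52 ± 1.23 CPM. IL6 fell from 28.8 ± 0.879 to 13.5 ± 0.402 CPM (-1.10 ± 0.18, adjusted p = 0.00898). MMP1 (hg19 chromosome 11, 102660651 to 102668891) fell from 802 ± 116 to 331 ± 30.9 CPM (-1.28 ± 0.17, adjusted p = 0.00371). SERPINB2, plasminogen activator inhibitor 2, fell from 201 ± 48.6 to 34.2 ± 10.7 CPM. CCL2 fell from 254 ± 2.92 to 148 ± 3.19 CPM (-0.78 ± 0.14, adjusted p = 0.016), a call lost without inhibitor-treated 11 or inhibitor-treated 24 (adjusted p up to 0.0755). CSF2, the granulocyte-macrophage growth factor, was near the detection floor, at 0.12 ± 0.0994 against 0.96 ± 0.0396 CPM (-2.91 ± 0.66, adjusted p = 0.041), and its call was lost when any of the 4 libraries compared was left out (adjusted p up to 0.252). Its log2 fold change was -4.10 without inhibitor-treated 11 and -2.29 without inhibitor-treated 24. The plasminogen activator PLAT rose from 293 ± 13.1 to 417 ± 24.3 CPM. The metalloproteinase inhibitor gene TIMP1 rose from 2510 ± 84.2 to 4100 ± 43.6 CPM (0.71 ± 0.13, adjusted p = 0.0157, lost without senescent 11, senescent 24 or inhibitor-treated 24, adjusted p up to 0.088). Of the 31 messenger RNAs with AU-rich elements 16 fell and 2 rose, or 19 and 3 adjusted over the list alone (median -0.78, camera adjusted p = 2.21e-42), and the call held with an estimated correlation (adjusted p = 0.0204). IL24, one of them, fell from 3.01 ± 0.288 to 0.124 ± 0.108 CPM, near the detection floor with 1 and 4 counts in the treated libraries. Its log2 fold change of -4.56 was -3.87 without inhibitor-treated 11 and -5.81 without inhibitor-treated 24. NF-kB feedback targets fell in 6 of 23, or 12 adjusted over the list alone (median -0.33, camera adjusted p = 6.45e-09, and adjusted p = 0.0827 with an estimated correlation). SOD2 fell from 872 ± 70.1 to 457 ± 33.1 CPM.

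Of 40 cell-cycle genes 26 rose and none fell, or 37 and 0 adjusted over the list alone (median 1.09, camera adjusted p = 7.76e-52, and adjusted p = 0.131 with an estimated correlation). HMMR rose from 2.24 ± 0.729 to 7.50 ± 0.917 CPM, ANLN, an organiser of the cytokinetic ring, from 16.7 ± 5.46 to 49.0 ± 4.71 CPM, and BIRC5 from 4.55 ± 2.16 to 13.1 ± 2 CPM. MKI67 stood at 20.3 ± 0.658 against 9.07 ± 5.25 CPM without passing the test (1.17 ± 0.31, adjusted p = 0.0708). DNA replication genes rose in 9 of 39, or 23 adjusted over the list alone (median 0.48, camera adjusted p = 2.05e-15, and adjusted p = 0.0827 with an estimated correlation). TK1 went from 4.50 ± 2.09 to 14.4 ± 2.65 CPM. Histone genes rose in 10 of 26, or 15 with 1 lower adjusted over the list alone (median 0.52, camera adjusted p = 2.9e-13, and adjusted p = 0.292 with an estimated correlation). HIST1H1A rose from 2.30 ± 0.421 to 5.62 ± 0.192 CPM. Of the 17 lamina and chromatin genes 3 rose, or 9 adjusted over the list alone (median 0.32, camera adjusted p = 2.23e-06, and adjusted p = 0.0742 with an estimated correlation). HMGB2 rose from 12.2 ± 1.77 to 23.2 ± 1.07 CPM. LMNB1 rose from 6.25 ± 1.6 to 11.5 ± 1.06 CPM (0.88 ± 0.17, adjusted p = 0.0206), a call lost without senescent 24 or inhibitor-treated 11 (adjusted p up to 0.0972). The p53 targets did not pass the test as a list, with 1 of 30 higher and 1 lower, or 1 and 2 adjusted over the list alone (median -0.04, camera adjusted p = 0.57). GADD45A rose (0.48 ± 0.10) and FAS fell (-0.45 ± 0.08). GADD45A lost its call without senescent 11, inhibitor-treated 11 or inhibitor-treated 24 (adjusted p up to 0.195). FAS lost its call without senescent 24, inhibitor-treated 11 or inhibitor-treated 24 (adjusted p up to 0.114). MDM2 stood at 481 ± 9.27 against 451 ± 41.4 CPM (adjusted p = 0.725).

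The largest single rise by the fixed rule was that of MAP2K6, from 2 ± 0.922 to 15.5 ± 3.77 CPM (2.93 ± 0.28, adjusted p = 0.000641). MAPK14 stood at 85.2 ± 0.816 against 81.1 ± 3.16 CPM (adjusted p = 0.724). Among the largest drops were CGA, the shared alpha subunit of the glycoprotein hormones, from 5.03 ± 2.11 to 0.317 ± 0.0237 CPM (-3.97 ± 0.41), and CHI3L1 from 16.4 ± 1.97 to 2.33 ± 0.459 CPM. Others were OLFM2 from 21.5 ± 7.65 to 3.31 ± 1.11 CPM, xanthine dehydrogenase (XDH) from 50.6 ± 0.493 to 8.48 ± 0.4 CPM and TNFSF18 from 35.2 ± 5.26 to 6.42 ± 1.37 CPM. Targets of the aryl hydrocarbon receptor, a ligand-activated transcription factor, fell in 4 of 5 measured genes, also adjusted over the list alone (median -0.56, camera adjusted p = 2.1e-14), and this held with an estimated correlation (adjusted p = 0.0302). In this list CYP1B1 fell from 28.5 ± 1.27 to 7.96 ± 1.62 CPM and TIPARP from 145 ± 1.48 to 64.6 ± 0.9 CPM. AHRR and SLC7A5 fell by less, with log2 fold changes of -0.53 and -0.56. With 1 library left out these ran from -0.56 to -0.49 and from -0.76 to -0.38. Collagen and matrix genes fell in 9 of 33, or 13 adjusted over the list alone (median -0.25, camera adjusted p = 1.14e-12), which also held with an estimated correlation (adjusted p = 0.0302). TNC went from 1110 ± 116 to 489 ± 56 CPM, COL8A1 from 299 ± 6.02 to 128 ± 7.09 CPM and ASPN from 6.61 ± 0.651 to 1.49 ± 0.191 CPM. Cholesterol and fatty acid synthesis genes rose in 9 of 32, or 11 adjusted over the list alone (median 0.24, camera adjusted p = 4.8e-09, and adjusted p = 0.266 with an estimated correlation).

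Interferon-stimulated genes had a median log2 fold change of 1.13 with the inhibitor, and 1 of 35 was called higher over all genes against 29 adjusted over the list alone (camera adjusted p = 5.63e-15, and adjusted p = 0.362 with an estimated correlation). With the replicate number as a block, 28 of the 35 were called higher over all genes. The libraries of a state differed widely here. The called gene, MX2, stood at 46 ± 35.1 against 11.4 ± 4.71 CPM (adjusted p = 0.042). It lost its call without young 11, young 24, senescent 24 or inhibitor-treated 11 (adjusted p up to 0.137). Over the 35 genes the median log2 difference between libraries 11 and 24 of a state was 0.06 in young, 0.51 in senescent and 1.30 in inhibitor-treated cells.

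Of the cell-type markers, none of 9 keratinocyte and none of 7 leukocyte markers was called, and of 16 fibroblast markers 4 fell and 1 rose, or 5 and 2 adjusted over the list alone (median -0.21, camera adjusted p = 0.00229, and adjusted p = 0.266 with an estimated correlation). All 661 called genes had the same sign in both replicate numbers, which the calling from these libraries again favours. The count of called genes fell by more than 1.5 times when a compared library was left out, to 421 without senescent 11, 350 without senescent 24, 316 without inhibitor-treated 11 and 384 without inhibitor-treated 24. Of the 79 called genes named for this comparison by the fixed rule, 44 kept their call in each of the 6 such fits.

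**Figure D2:**
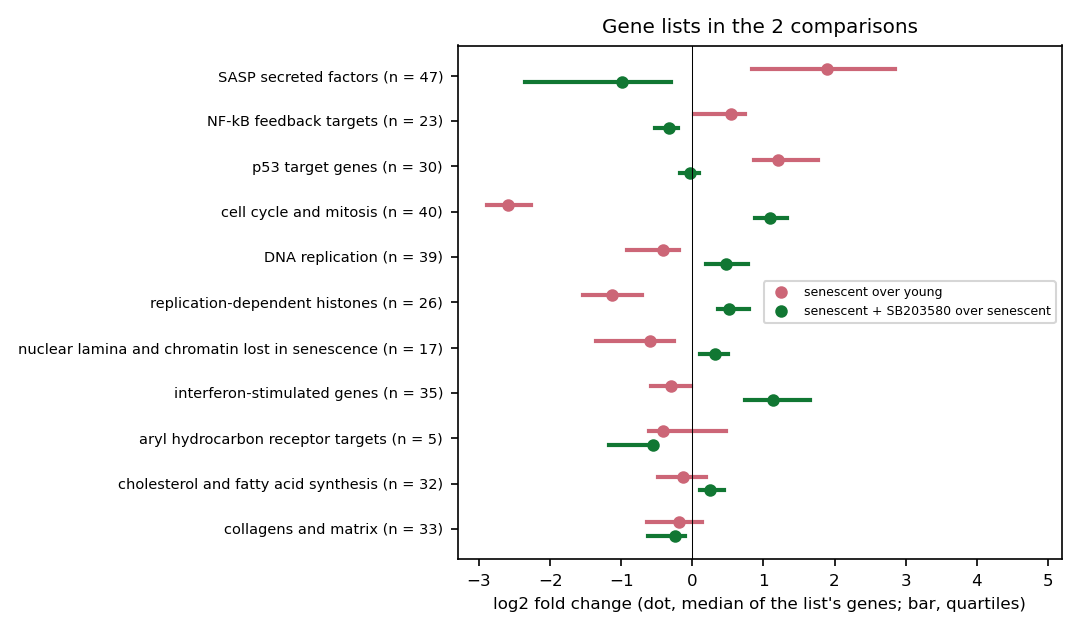
For 11 gene lists, the horizontal axis gives the log2 fold change of senescent over young cells (red) and of SB203580-treated over untreated senescent cells (green), with the median of the list's genes as a dot and the quartiles as a bar. The SASP median was 1.89 and then -0.99, the cell-cycle median -2.60 and then 1.09, and the p53 target median 1.21 and then -0.04.

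The last comparison asked what still set treated senescent cells apart from young ones. The p53 targets and the cell-cycle genes did. Of 30 p53 targets 28 were higher than in young cells, as adjusted over the list alone (median 1.15, camera adjusted p = 3.76e-52, and adjusted p = 0.156 with an estimated correlation). CDKN1A stood at 1190 ± 98.1 against 242 ± 1.84 CPM (2.31 ± 0.13, adjusted p = 1.05e-05) and MDM2 at 481 ± 9.27 against 95.1 ± 9.79 CPM. All 40 cell-cycle genes were lower, also adjusted over the list alone (median -1.41, camera adjusted p = 8.62e-44, and adjusted p = 0.193 with an estimated correlation). MKI67 stood at 20.3 ± 0.658 against 82.7 ± 21.4 CPM (-2.03 ± 0.28, adjusted p = 0.00081). In all 2050 genes were called higher and 1915 lower than in young cells, 479 and 557 of them by more than 2-fold. Of 28 lists 16 were called by camera, 0 by camera with an estimated correlation and 13 by fry.

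SASP genes were higher than in young cells in 22 of 47 and lower in 6, or 25 and 10 adjusted over the list alone (median 0.60, camera adjusted p = 5.08e-08, and adjusted p = 0.193 with an estimated correlation). LIF stood at 20.6 ± 4.51 against 3.21 ± 1.4 CPM, osteopontin (SPP1) at 17.6 ± 9.68 against 1.44 ± 0.0595 CPM (log2 fold change 3.60, and 2.89 without inhibitor-treated 11) and PLAT at 417 ± 24.3 against 68.7 ± 9.45 CPM. IL6, at 13.5 ± 0.402 against 13.2 ± 4.24 CPM (0.03 ± 0.18, adjusted p = 0.912), and IL8 (0.78 ± 0.26, adjusted p = 0.056) did not pass the test. CXCL1 did (0.66 ± 0.20, adjusted p = 0.037), but not without young 11, young 24 or inhibitor-treated 11 (adjusted p up to 0.346). Messenger RNAs with AU-rich elements were higher in 12 of 31 and lower in 5, or 15 and 6 adjusted over the list alone (median 0.50, camera adjusted p = 0.00011, and adjusted p = 0.228 with an estimated correlation). Cyclin D1 (CCND1) stood at 2500 ± 459 against 235 ± 22.1 CPM. MAP2K6 stood at 15.5 ± 3.77 against 17.6 ± 3.25 CPM (adjusted p = 0.598). ZFP36 remained lower, at 10 ± 0.101 against 20.7 ± 0.557 CPM (-1.05 ± 0.11, adjusted p = 0.000237). CDKN2A (-0.72 ± 0.21, adjusted p = 0.0314) and HNRNPD (-0.48 ± 0.15, adjusted p = 0.0455) were called lower. The call of CDKN2A was lost without young 11, young 24 or inhibitor-treated 11 (adjusted p up to 0.212). That of HNRNPD was lost without young 11, young 24 or inhibitor-treated 24 (adjusted p up to 0.287).

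LMNB1 at 11.5 ± 1.06 against 28.5 ± 1.45 CPM and HMGB2 at 23.2 ± 1.07 against 56.7 ± 2.47 CPM were among 8 lower lamina and chromatin genes of 17, also adjusted over the list alone (camera adjusted p = 0.000157, and adjusted p = 0.156 with an estimated correlation). Histone genes were lower in 15 of 26 and higher in 2, or 18 and 2 adjusted over the list alone (median -0.53, camera adjusted p = 8.25e-07, and adjusted p = 0.475 with an estimated correlation). DNA replication genes were higher in 4 and lower in 3 of 39 and did not pass the test as a list (4 and 2 adjusted over the list alone, median -0.03 but mean 0.02, camera adjusted p = 0.64). Collagen and matrix genes were lower in 18 of 33 and higher in 1, or 20 and 2 adjusted over the list alone (median -0.58, camera adjusted p = 7.71e-14, and adjusted p = 0.0831 with an estimated correlation). FBN2 stood at 404 ± 22.1 against 1260 ± 270 CPM. All 5 aryl hydrocarbon receptor targets were lower, also adjusted over the list alone (median -0.97, camera adjusted p = 6.05e-08, and adjusted p = 0.149 with an estimated correlation). Lysosome genes were higher in 12 of 27, or 15 with 1 lower adjusted over the list alone (camera adjusted p = 3.91e-05, and adjusted p = 0.21 with an estimated correlation). FUCA1 stood at 39 ± 1.32 against 15.3 ± 1.49 CPM. Interferon-stimulated genes were higher in 9 of 35, also adjusted over the list alone (median 0.83, camera adjusted p = 0.00204, and adjusted p = 0.609 with an estimated correlation). The call was lost without inhibitor-treated 11 (adjusted p = 0.983).

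Among the largest single differences from young cells were CLCA2 at 60.4 ± 17.7 against 2.61 ± 0.644 CPM, cyclin D2 (CCND2) at 31 ± 3.58 against 3.07 ± 1.25 CPM, and ESM1 at 26.1 ± 3.2 against 3.05 ± 1.63 CPM. Lower were WNT2 at 4.47 ± 3.15 against 63.1 ± 26.3 CPM, OMD at 0.32 ± 0.183 against 6.1 ± 1.14 CPM and ASPN at 1.49 ± 0.191 against 14.9 ± 2.94 CPM. With 1 library left out the log2 fold change of ESM1 (3.11) ran from 2.64 to 3.79 and that of OMD (-4.23) from -4.94 to -3.74. That of WNT2 moved from -3.83 to -3.23 without inhibitor-treated 11 and to -4.80 without inhibitor-treated 24. The same sign in both replicate numbers was seen for 3964 of 3965 called genes, which the calling again favours. With total counts in place of TMM factors 1541 genes were called higher and 2328 lower, against 2050 and 1915. Without inhibitor-treated 11 the count of called genes was 2007.

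The genes called in both comparisons that involve the senescent libraries ran mainly in opposite directions. Of the 37 SASP genes raised in senescence 25 were called lower with SB203580, 10 were not called (among them CCL20, GDF15, ICAM1, LIF and SPP1) and 2 were called higher (PLAT and TIMP1). Of the 25 lowered genes, 12 were still higher than in young cells, 11 were not called against young, and IGFBP5 and TNFRSF11B were called lower than in young. Over all genes, 193 were called higher in senescence and lower with the inhibitor. By the size of the drop IL24, CGA, CXCL1, IL8, CXCL6, IL1A, CSF3, CCL8, SST and CSF2 led them, of which IL24 moved from -4.56 to -5.81 without inhibitor-treated 24 and to -3.87 without inhibitor-treated 11. SST moved from -2.96 to -2.35 without senescent 24, and CSF2 from -2.91 to -4.10 without inhibitor-treated 11 and to -2.29 without inhibitor-treated 24. The inhibitor call was lost without either inhibitor-treated library for CCL8 (adjusted p up to 0.0675), without senescent 24 or inhibitor-treated 24 for SST (up to 0.087), and without any of the 4 libraries compared for CSF2 (up to 0.252). The senescence call was lost without young 11 or senescent 11 for CSF2 (adjusted p up to 0.114), and for CCL8 also without senescent 24 (up to 0.12). In the mirror direction 227 genes were called lower in senescence and higher with the inhibitor, led by MAP2K6, GLYATL2, NEK2, HMMR, TK1, CDK1, NCAPH, ANLN, FAM64A and PDE1A. NCAPH lost the inhibitor call without senescent 24, and its value of 1.62 ran from 1.16 to 2.21 with 1 library left out. NEK2 moved from 1.78 to 3.0 without senescent 11 and to 1.08 without senescent 24. It lost the inhibitor call without young 11, young 24, senescent 24 or inhibitor-treated 11 (adjusted p up to 0.17).

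The share of senescence calls met by an opposite inhibitor call was small, 8.72% of the 2213 higher genes and 10.7% of the 2119 lower ones. The median log2 fold change with the inhibitor was -0.12 over the former and 0.16 over the latter. The smaller number of inhibitor calls limits these shares. Of the 316 genes called lower with the inhibitor, 61.1% were called higher in senescence. Of the 345 called higher with it, 65.8% were called lower in senescence. Independent lists of these sizes would share 42.9 and 44.9 genes. Because both comparisons use the senescent libraries, part of the excess can come from them. The correlation of the fold changes across 16290 genes, which are not independent replicates, was -0.43 against a simulated -0.50. Such a correlation arises in unchanged groups at any noise level, so it does not show how much comes from the shared libraries. The covariance was -0.129 against a simulated -0.0351, a difference of -0.0935. With 1 senescent library set against young and the other against the inhibitor, so that none was shared, the counts for the first direction were 113 and 94 for the 2 ways of assigning them, and the covariances -0.0928 and -0.0841. The correlations of the fold changes were then -0.26 and -0.23. Of the genes higher in senescence 1441 were also higher than young with the inhibitor. Both of these comparisons share the young libraries, and their fold changes correlated across genes at 0.82 against a simulated 0.50, with a covariance of 0.390 against a simulated 0.0344. The count of 193 fell by more than 1.5 times, to 122 without senescent 11, 115 without senescent 24, 102 without inhibitor-treated 11 and 109 without inhibitor-treated 24. The mirror count of 227 fell to 119 without senescent 24, 134 without inhibitor-treated 11 and 127 without inhibitor-treated 24.

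**Figure D3:**
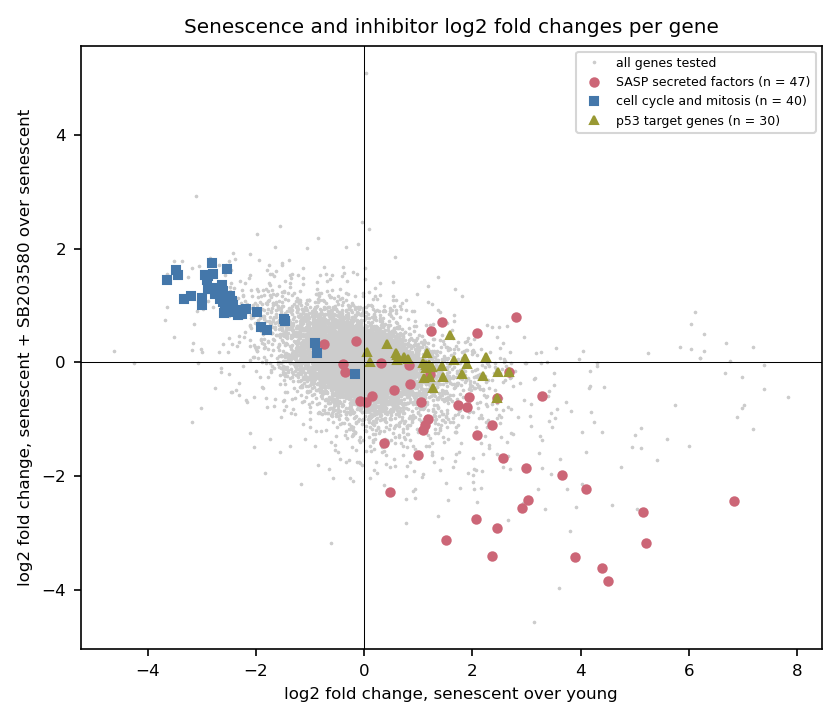
Each point is a gene, with the log2 fold change of senescent over young cells on the horizontal axis and of SB203580-treated over untreated senescent cells on the vertical axis, for all genes (grey), SASP genes (red circles, n = 47), cell-cycle genes (blue squares, n = 40) and p53 targets (olive triangles, n = 30). The axes share the senescent libraries, which tilts the grey cloud downwards even without any effect (covariance -0.0351 simulated, -0.129 observed). SASP genes lie mainly at the lower right and cell-cycle genes at the upper left, while p53 targets lie to the right near 0 on the vertical axis (median -0.04).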

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

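The fits without a shared senescent library and without 6 abundant non-messenger RNAs were chosen after seeing the data. No named gene or list turned its direction under the alternatives run, while with total counts only the balance of higher and lower calls turned in all 3 comparisons. With the replicate number as a block, the inhibitor against senescent count was 1611 in place of 661, the senescence-induced genes lowered by the inhibitor 440 in place of 193 and the mirror count 503 in place of 227, while the other 2 counts (5707 and 5460) stayed within 1.5 times, no list lost its call, and 28 of 35 interferon-stimulated genes were called higher with the inhibitor in place of 1. The labels do not say that the numbers mark a shared day or culture. Deviations of libraries 11 from 24 correlated across genes at 0.20 between young and senescent, 0.13 between young and inhibitor-treated and 0.29 between senescent and inhibitor-treated (0.37, 0.22 and 0.64 over 4889 genes with a mean log2 CPM over 5). On the third axis of a principal component analysis (12.1% of the variance), all libraries numbered 11 were positive (14.6 to 17.2) and all numbered 24 negative (-14.0 to -19.6). RN7SL1 took 7.60 to 8.01% of counts in the libraries numbered 11 and 9.32 to 9.61% in those numbered 24. Without a low-count filter the same 3 counts were 1343, 335 and 409, with 656 of the 661 genes among the 1343; the cause was not tested. Leaving out 1 library at a time, which leaves fewer samples, gave 316 to 712 genes for the inhibitor against senescent, 2007 to 3910 for the inhibitor against young, 102 to 188 induced genes lowered and 119 to 218 in the mirror direction. With no shared senescent library the last 2 counts were 113 and 129, or 94 and 93 with the libraries exchanged. With an estimated correlation the lists called fell from 13 to 0 for senescent against young, from 15 to 4 for the inhibitor against senescent and from 16 to 0 for the inhibitor against young, and fry kept 32 of the 44 list calls. DESeq2 called 3353, 704 and 3111 genes, and 29 of 360 values of named genes lost a call with it. Other settings kept every count within 1.5 times, among them the SASP genes lowered by the inhibitor. The planned limma tests on FPKM values gave no value, because those values are not on the FPKM scale and only 244 of 11877 expressed genes are named in all 6 tables. Depth and 2 libraries per state limit the calling of changes under 2-fold. Simulated 1.5-fold changes were called in 36 to 42%, with fewer calls and so a stricter adjusted threshold than in the data.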

Other observations

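The tests of explanations in this part were chosen after the results they bear on were seen, while the gene lists and their tests were not. With the inhibitor, cytosolic ribosomal protein genes had a median log2 fold change of 0.33 over 33 genes, with none called over all genes and 7 adjusted over the list alone (camera adjusted p = 4.41e-10, and adjusted p = 0.47 with an estimated correlation). Mitochondrially encoded messenger RNAs had a median of 0.33 over 12 genes, none called over all genes and 2 adjusted over the list alone (camera adjusted p = 0.000151, and adjusted p = 0.47 with an estimated correlation), and this list lost its call without inhibitor-treated 24 (adjusted p = 0.103), the library with the highest share of counts in the 2 most abundant entries named by a clone identifier (13.5%, against 8.52 to 10.8% in the others). Metalloproteinases and their inhibitors fell in 3 of 16 and rose in 1, or 6 and 3 adjusted over the list alone (median -0.06, camera adjusted p = 0.0234, and adjusted p = 0.266 with an estimated correlation). This call was lost without senescent 11 (adjusted p = 0.0878) and without inhibitor-treated 24 (adjusted p = 0.08). ADAMTS1 went from 342 ± 14.5 to 171 ± 14.3 CPM and TIMP3 from 2170 ± 157 to 1170 ± 67.4 CPM. Against young cells, the inhibitor-treated cells were lower in 7 of 16 RNA-binding regulators of AU-rich elements (7 adjusted over the list alone, camera adjusted p = 0.0111, and adjusted p = 0.543 with an estimated correlation) and in 8 of 19 contractile genes, 9 adjusted over the list alone, such as ACTG2 at 0.859 ± 0.271 against 6.15 ± 0.361 CPM (camera adjusted p = 0.0174, and adjusted p = 0.582 with an estimated correlation). The contractile list lost its call without young 24 (adjusted p = 0.0868) and without inhibitor-treated 24 (adjusted p = 0.207). Immediate-early genes were higher in 11 of 29 and lower in 7, or 12 and 8 adjusted over the list alone (median 0.23 but mean -0.00106, test upward, camera adjusted p = 0.00576, and adjusted p = 0.193 with an estimated correlation), a call lost without young 24 (adjusted p = 0.0849). Ribosomal protein genes were higher in 5 of 33, or 2 adjusted over the list alone (camera adjusted p = 0.00147, and adjusted p = 0.609 with an estimated correlation), a call lost without young 11 (adjusted p = 0.113) and without inhibitor-treated 24 (adjusted p = 0.0579). Fibroblast markers were lower in 5 of 16 and higher in 2, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.0186, and adjusted p = 0.426 with an estimated correlation), a call lost without inhibitor-treated 11 (adjusted p = 0.0873). Mitochondrially encoded messenger RNAs were higher in 4 of 12, also adjusted over the list alone (camera adjusted p = 0.012, and adjusted p = 0.582 with an estimated correlation), a call lost without young 24 (adjusted p = 0.0869) and without inhibitor-treated 24 (adjusted p = 0.2).

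With the inhibitor 26 of 40 cell-cycle genes were called higher (adjusted p = 0.131 with an estimated correlation), while the p53 targets had a median log2 fold change of -0.04. The 39 cell-cycle genes called lower in senescence closed a median of 22.4% of their gap to young CPM (quartiles 19.3 and 27.9%), which a share of young-like cells among the treated ones could give. Such a share would lower the 28 p53 targets by a median of 0.20 on the log2 scale, but they closed a median of 5.21% of their gap (quartiles -10.0 and 14.9%). Of the 28 genes 5 fell by as much as needed. The test cannot decide, because the inhibitor itself may move p53 targets in the other cells. The drop needed is also close to the median SE over all genes tested (0.149), which is not that of the p53 targets. With total counts only the cell-cycle median was 1.07 and 39 of 40 genes were above 0. This argues against the TMM factors as the source of the rise. The test is narrow, because the 2 scalings differed little. Over all genes the median log2 fold change was -0.029 with total counts and -0.00204 with TMM factors. A response of some or all senescent cells to the SB203580 treatment stays open beside such a share, as a hypothesis, with the number of dividing cells not measured here. Whether it would run through p38 was not tested.

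Interferon-stimulated genes had a median log2 fold change of 1.13 with the inhibitor, with 1 of 35 called higher over all genes (adjusted p = 0.362 with an estimated correlation) and 28 with the replicate number as a block. With total counts only the median was 1.12 and 34 of 35 genes were above 0. The use of TMM factors thus does not account for the rise. The difference may still come from the libraries and not the inhibitor: inhibitor-treated 24 exceeded senescent 11 by a median log2 difference of only 0.0524 (20 of 35 genes), while between libraries of the same number it was 1.23 (34 of 35) and 0.73 (35 of 35). Which reading holds depends on whether libraries of the same number belong together. With 2 libraries per state and numbers whose meaning the labels do not give, these cannot be told apart.

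In 30 genes both young libraries had 0 counts and all 4 senescent and inhibitor-treated libraries at least 5, against 0 genes for the same pattern in senescent or in inhibitor-treated libraries; among them RYR2 had 18 to 36 counts and CNTNAP2 14 to 26, and 22 of the 29 with a known span covered at least 100 kb. Over 276 low-count protein-coding genes of 300 kb or more, counts per kb of exon were 0.399 and 0.377 in young and 0.914, 0.911, 0.859 and 0.718 in the other libraries, against 1.58 and 1.28 and then 1.38, 1.5, 1.43 and 1.3 over 3085 such genes under 30 kb. Genomic DNA is argued against, since 380 olfactory receptor genes gained 0.00885 counts per kb of exon where the long genes gained 0.463. Exon length is argued against, since among genes with 5 to 10 kb of exon those of 300 kb or more were at 2.08 times the young level and those under 30 kb at 0.903 times. Unspliced RNA, reads from outside these genes and a difference in transcription between senescent and young cells stay open and untested, because reads were not analysed here.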
